A study of Mus musculus with 8 samples.

How the data were processed

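RNA of 8 MC3T3 samples was sequenced, 4 under the LLC_CM label and 4 under the NCM label, from poly(A)-selected libraries made with 200 ng of input RNA and 12 PCR cycles, per the labels' protocols. The deposited file holds raw read counts per gene for the 8 libraries, as whole numbers. Per the submitters' processing notes, CASAVA, STAR, featureCounts and the mm10 genome build were used, with versions not given in the sources used here. The library kit named in the labels' protocols does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

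Columns were assigned to samples by name, and groups and replicate numbers came from the sample titles. The table lists 43346 genes, of which 22913 had a read and 14991 passed edgeR's filterByExpr for the group design. Library totals ran from 27264212 to 35573953 counts. Of the table's genes 42462 were found by identifier in GENCODE M21, and 33497 had the same chromosome, start and end there. That annotation was used for exon overlaps, transcript GC content and transcript length, while gene coordinates come from the deposited table. The 2 libraries of any pair within a group differed by more than sampling noise, with a chi-square of at least 7.12 per degree of freedom over genes with 20 or more summed counts, so none was treated as a repeat deposit.

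The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors, robust dispersion and quasi-likelihood estimation, no covariate, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Fold changes are LLC_CM minus NCM on the log2 scale, and standard errors are the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled totals, and log2 CPM for the principal components used a prior count of 2. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

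Gene lists numbered 29, written from general knowledge of bone cells and of stress, immune and metabolic responses, and 25 had at least 3 tested members. Each was tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Camera called 5 lists up and 7 down, and 4 of these 12 calls held with an estimated correlation: bone matrix, chemokine and NF-kB, matrix protease and chondrocyte genes. Named genes were, first, the 10 highest and 10 lowest log2 fold changes among genes past 0.05 with a mean of at least 5 CPM, separated groups and no predicted-model symbol. They also include up to 3 members per list with the smallest adjusted p, or the most abundant member of at least 1 CPM where none passed, and 13 bone genes chosen in advance. Sparc, Postn, Mgp, Slc20a2, Ackr3, Pdpn, Irx5, Axin2, Lef1, Ccl2, Il6, Ccl9, Vcam1, Xaf1, Timp3 and Col3a1, the members given as not past the threshold (Cbfb, Msx2, Nfkbia and Nfkb2), Col1a2, and the genes that only the additional observations name were chosen after their values were seen. Some genes that the rule names are not reported here.

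The fit was tested on simulated counts drawn from the means, library sizes and dispersions of the 14991 genes of LLC_CM against NCM. With 200 genes changed, the test recovered 36% of the genes changed by 0.32 on the log2 scale, 72% of the genes changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 4-fold, and called 9 unchanged genes. With no gene changed it called 1 gene, and camera called 0 of 25 unchanged lists. Genes were simulated independently of each other and those lists were drawn at random. The simulation therefore cannot show how often camera calls an unchanged list of correlated genes, such as interferon genes (estimated correlation 0.43). It also changed 200 genes, where 5531 were called in the data.

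Alternatives were DESeq2 size factors, upper-quartile factors or library size alone in the same fit, no low-count filter, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, an adjusted p of 0.01, a test against a 2-fold change, camera with an estimated correlation, and fry. Added after seeing the data were the odd or even replicate number as a term, the odd-numbered or even-numbered libraries alone, and the bone matrix list without Bglap and Bglap2. Sequence matches used blastn 2.17.0. Intervals of medians are 95% bootstrap intervals from 1000 resamples of genes. They treat the genes of a list as independent and hold no spread between libraries, so they may be too narrow.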

Results

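RNA was sequenced from MC3T3 cells, a mouse pre-osteoblast line that lays down bone-like matrix in culture, after 7 days in mineralizing medium with 10 mM beta-glycerophosphate and 100 ug/mL ascorbic acid. One group of 4 libraries, LLC_CM, received 25% medium conditioned by LLC1 cells, a mouse Lewis lung carcinoma line. The other 4 libraries, named NCM, are taken here as the vehicle group by elimination, because the labels do not spell the abbreviation out. The comparison asks how soluble products of lung carcinoma cells alter gene expression in mineralizing osteoblasts. The count table gave between 27264212 and 35573953 assigned reads per library, and between 18913 and 19317 genes had at least 1 read. A count of 0 allowed up to 0.110 CPM in the shallowest library, at 3 counts per library, which covers counting error only. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

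The LLC_CM and NCM libraries formed 2 separate groups. The first principal component of log2 CPM held 76.4% of the variance and separated LLC_CM from NCM, and the next held 6.5%. Pearson correlations across genes were 0.989 to 0.993 within groups and 0.943 to 0.963 between groups, and genes are not independent replicates. Col1a2, which encodes a chain of type I collagen, took the largest share of reads in every library, 2.41% to 2.99% in LLC_CM and 3.64% to 4.76% in NCM.

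**Figure D1:**
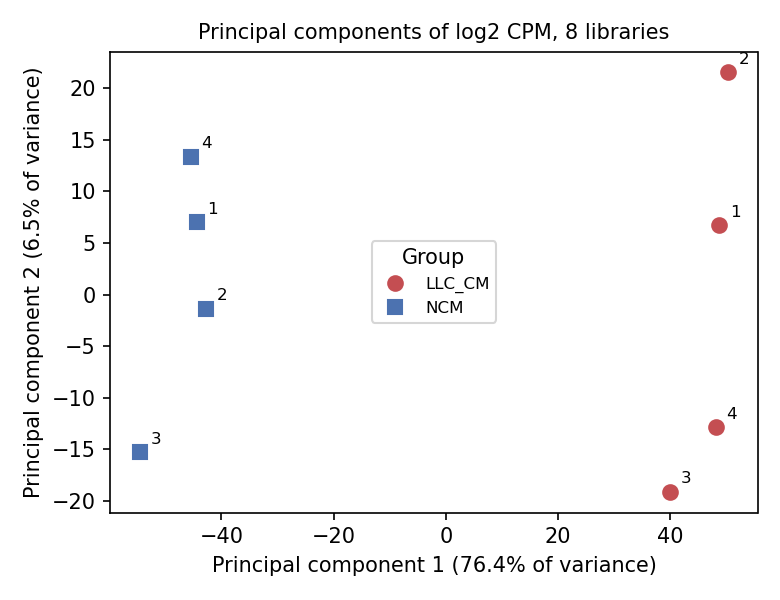
Principal components 1 and 2 of log2 CPM for the 8 libraries, with axes in component units and numbers giving the replicate. The 4 LLC_CM libraries (circles) lie on one side of component 1, which holds 76.4% of the variance, and the 4 NCM libraries (squares) on the other.

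Mineralization genes were among the most strongly lowered in LLC_CM, and acute phase and complement genes among the most strongly raised. Bglap, which encodes osteocalcin, was 81.8-fold lower in LLC_CM, at 1.55 ± 0.28 CPM against 128 ± 33.2 CPM in NCM (SD, n = 4). C3, the central complement component, was 71.0-fold higher, at 696 ± 95.7 CPM against 9.80 ± 1.11 CPM (SD, n = 4). Mmp13, a collagenase of bone and cartilage, rose 25.7-fold from 290 ± 21.2 to 7466 ± 728 CPM (SD, n = 4). Of 14991 genes tested, 5531 (36.9%) changed at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 2814 higher and 2717 lower in LLC_CM. Among them 748 were at least 2-fold higher and 543 at least 2-fold lower, 1291 together, and 785 passed a test against a 2-fold change itself. All 4 values of one group lay beyond all 4 of the other for 5449 genes, 36.3% of those tested against 2.86% by chance.

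The 10 named genes with the lowest log2 fold changes were Col22a1, Adamts18, Grhl3, Bglap3, Prex1, Enthd1, Bglap, Bglap2, Slc6a4 and Col11a2. Col22a1 (ENSMUSG00000079022, chromosome 15, 71795795 to 72034227 in mm10), a collagen of tissue junctions, fell by 9.50 ± 0.27 on the log2 scale (SE, edgeR, adjusted p = 2.2e-11). Adamts18 (chromosome 8, 113697126 to 113848615), a secreted metalloprotease, fell by 9.17 ± 0.20 (adjusted p = 3.8e-13). Slc6a4, the serotonin transporter, fell by 6.03 ± 0.20 (adjusted p = 7.3e-12) and Col11a2, a fibrillar collagen chain of cartilage, fell by 5.99 ± 0.19 (adjusted p = 6.6e-10). The 10 highest were C4b, Serpina3n, Wfdc21, Serpina3m, C3, Vtn, Lcn2, Ggt5, Lbp and Tarm1. C4b (chromosome 17, 34728380 to 34743882), a complement C4 gene, rose by 9.14 ± 0.18 and Serpina3n (chromosome 12, 104406729 to 104414329), a protease inhibitor, by 8.78 ± 0.15 (adjusted p = 3.2e-13 and 4.4e-14). Transcripts of C4b matched C4a at 95.97% identity, those of Serpina3m matched Serpina3k at 90.23%, and those of Bglap matched Bglap2 at 98.86% and Bglap3 at 96.36%, so the split of reads between the members of each set is uncertain.

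Osteoblast transcription factors were lower in LLC_CM. Of 9 tested osteoblast transcription factors, 7 fell and none rose, in the test over all genes and when adjusted over the list alone. Sp7, required for osteoblast formation, fell to 230 ± 24.0 CPM from 529 ± 44.8 CPM in NCM and Runx2, the lineage-defining factor, to 237 ± 14.1 CPM from 470 ± 31.2 CPM (SD, n = 4). Dlx3 had a log2 fold change of -2.63 ± 0.14 (SE). Cbfb (log2 fold change -0.13 ± 0.06) and Msx2 (0.09 ± 0.21) did not pass the threshold. The list moved down (camera, adjusted p = 9.8e-07), with adjusted p = 0.095 with an estimated correlation.

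Of 17 tested bone matrix and mineralization genes, 12 fell and 4 rose, with the same counts adjusted over the list alone. Bglap (ENSMUSG00000074483, chromosome 3, 88383501 to 88384464) and Bglap2 (chromosome 3, 88377736 to 88378699) fell, with log2 fold changes of -6.35 ± 0.22 and -6.28 ± 0.24. Ifitm5, a membrane protein of mineralizing osteoblasts, fell by 5.70 ± 0.18, Smpd3, a sphingomyelinase needed for bone mineralization, fell by 4.97 ± 0.17, and Phospho1, a matrix vesicle phosphatase, fell by 4.33 ± 0.14. Alpl, tissue-nonspecific alkaline phosphatase, fell by 2.19 ± 0.11 and was 4.55-fold lower. The abundant matrix genes moved less: Col1a1 fell by 0.49 ± 0.14 (adjusted p = 0.012), Ibsp fell by 0.45 ± 0.10 (adjusted p = 0.0020) and Sparc fell by 0.71 ± 0.10. Spp1, which encodes osteopontin, rose by 0.78 ± 0.12 and Postn, periostin, by 1.29 ± 0.16, while Mgp and Slc20a2 rose by 0.61 ± 0.10 and 0.56 ± 0.11. The list moved down (camera, adjusted p = 1.9e-13, and adjusted p = 0.031 with an estimated correlation). In the annotation 89.6% of the exonic length of Phospho1 overlapped Zfp652 and 84.2% overlapped Abi3 on the other strand, and 29.7% of that of Ifitm5 overlapped Gm45717, so their counts depend on how shared reads were assigned.

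Of 8 tested osteocyte markers, 5 fell and 2 rose, in both adjustments. Dmp1, Phex and Mepe, regulators of phosphate handling and mineralization in bone, had log2 fold changes of -3.26 ± 0.34, -3.03 ± 0.16 and -2.93 ± 0.21, Fam20c of -0.88 ± 0.09 and Ackr3 of -0.54 ± 0.17. Pdpn rose by 0.77 ± 0.10 and Irx5 by 0.26 ± 0.07. The list moved down (camera, adjusted p = 0.0031), with adjusted p = 0.070 with an estimated correlation. Sost, which encodes sclerostin, had 0 counts over the LLC_CM libraries and 1 over the NCM libraries, so it was not tested.

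**Figure D2:**
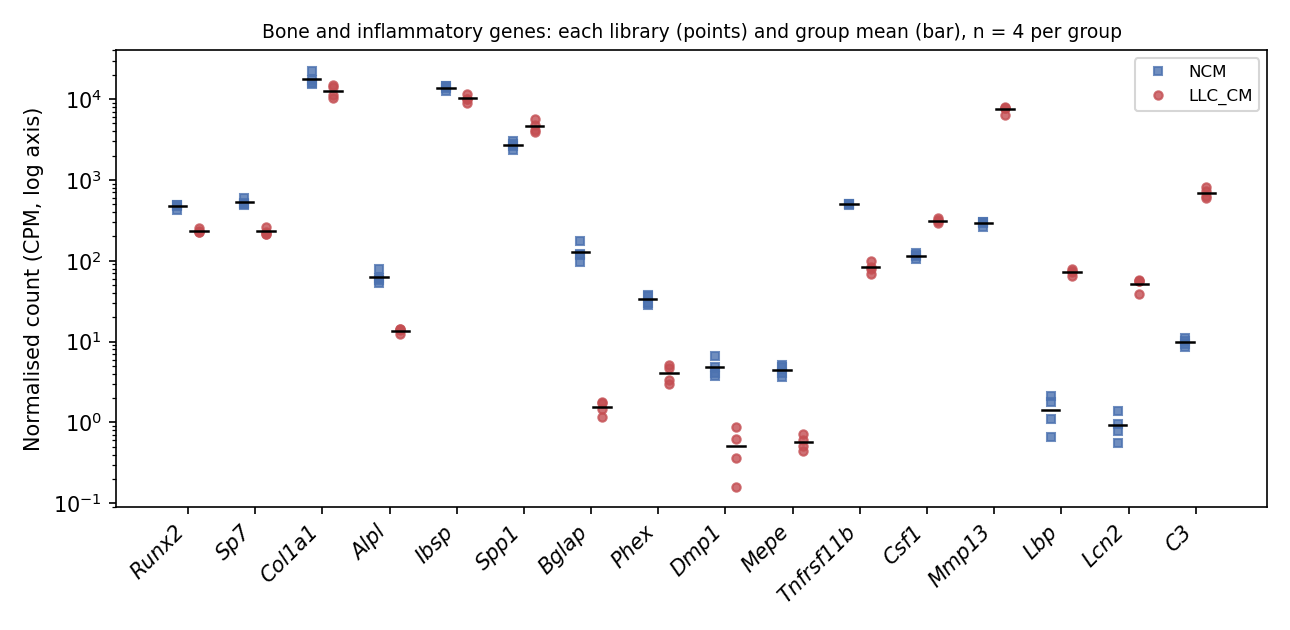
Normalised counts (CPM, log axis) of bone and inflammatory genes in each library (points) with the group mean (bar), 4 libraries per group. Bglap averaged 1.55 CPM in LLC_CM and 128 CPM in NCM, and Mmp13 averaged 7466 and 290 CPM.

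Secreted regulators of osteoclast formation changed in both directions. Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor for RANK ligand, was 6.07-fold lower in LLC_CM, at 82.8 ± 12.3 CPM against 503 ± 9.35 CPM (SD, n = 4, adjusted p = 1.5e-11). Csf1, the macrophage colony-stimulating factor that osteoclast precursors need, rose 2.73-fold (log2 1.45 ± 0.07), and the chemokine Cxcl12 rose by 1.28 ± 0.07. Ccl2 and Il6 rose by 3.44 ± 0.38 and 2.94 ± 0.52 from low levels, reaching 1.72 and 0.82 CPM. Lif fell by 2.29 ± 0.23, from 4.53 CPM in NCM to 0.92 CPM in LLC_CM. Sema3a and Wnt5a fell by 0.35 ± 0.09 and 0.34 ± 0.13. Of 9 tested members, 4 rose and 4 fell in both adjustments, and the list as a whole was not called (camera, adjusted p = 0.67). Its median log2 fold change was -0.24, its mean 0.36 and its test direction upward. Tnfsf11, which encodes RANK ligand, had 3 counts over LLC_CM and 0 over NCM, at or under the floor in both groups.

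Wnt target genes fell while several Wnt antagonists rose. Tcf7, a Wnt-responsive transcription factor, fell by 3.53 ± 0.15 on the log2 scale, and Notum and Znrf3, feedback inhibitors of the pathway, had log2 fold changes of -1.61 ± 0.19 and -0.80 ± 0.09. Axin2, a common readout of the pathway, fell by 0.30 ± 0.07, and Lef1 rose by 0.44 ± 0.13. Of 8 tested targets, 6 fell and 1 rose, and 7 fell when adjusted over the list alone. The list moved down (camera, adjusted p = 0.00038), with adjusted p = 0.13 with an estimated correlation. Of 6 tested antagonists, 4 rose and none fell in both adjustments, including Sfrp2 by 1.92 ± 0.17, Dkk2 by 0.88 ± 0.24 and Dkk3 by 0.58 ± 0.06. That list missed the threshold (camera, adjusted p = 0.053, and adjusted p = 0.13 with an estimated correlation). It passed without LLC_CM replicate 1 (0.048), NCM replicate 2 (0.027) or NCM replicate 3 (0.0039), but not without any other library, with up to 0.067. It also passed with the replicate number as a block (0.022), and with the odd or even replicate number as a term (0.039), chosen after seeing the data.

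BMP and TGF-beta response genes included strongly lowered members. Ctgf, a matricellular TGF-beta target, fell by 4.40 ± 0.14, Tgfb1 fell by 0.96 ± 0.10 and Skil fell by 0.78 ± 0.09. Of 11 tested TGF-beta targets, 6 fell and 1 rose in both adjustments (camera, down, adjusted p = 0.0015), with adjusted p = 0.057 with an estimated correlation. Among BMP targets and modulators, Bmper fell by 2.16 ± 0.11 and Bambi fell by 1.49 ± 0.13, while Atoh8 rose by 0.89 ± 0.11. Id2 rose by 0.54 ± 0.08, and Id1 (0.00 ± 0.19) and Id3 (-0.20 ± 0.11) did not pass the threshold. Of 14 tested, 5 fell and 3 rose in both adjustments, and the list was not called (camera, adjusted p = 0.19). An antisense gene model overlapped 23.2% of Ctgf.

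Chemokine, acute phase and NF-kB target genes rose together. Of 14 tested, 12 rose and none fell, in both adjustments, and the list moved up (camera, adjusted p = 3.1e-17, and adjusted p = 0.00996 with an estimated correlation). Besides C3, Lcn2, the iron-binding protein lipocalin 2, rose 56.0-fold to 52.2 ± 9.16 CPM (SD, n = 4), Ccl9 rose by 5.09 ± 0.40 and Vcam1, an adhesion molecule, by 2.32 ± 0.13. Saa3, a serum amyloid gene, had 938 counts over LLC_CM and 1 over NCM, a ratio of 867 with an exact 95% counting interval of 155 to 34261. The NF-kB inhibitor gene Nfkbia (0.00 ± 0.07) and Nfkb2 (0.21 ± 0.10) did not pass the threshold. The macrophage markers Lyz2 and Fcer1g were also higher in LLC_CM, by 0.81 ± 0.21 and 1.54 ± 0.28.

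Interferon-stimulated genes were higher in LLC_CM. Of 19 tested, 17 rose and 1 fell in both adjustments, with Ifit1 up by 3.69 ± 0.28 and Ifit3 by 2.71 ± 0.23. Xaf1 fell by 0.68 ± 0.12. The list moved up (camera, adjusted p = 4.3e-09), with adjusted p = 0.13 with an estimated correlation.

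Matrix proteases and a list of other collagens and matrix glycoproteins moved up. Of 13 tested proteases and inhibitors, 9 rose and 1 fell in both adjustments. Mmp8, a neutrophil-type collagenase, rose by 3.69 ± 0.21 and Adamts1 by 1.17 ± 0.09, and Timp3, a protease inhibitor, fell by 0.30 ± 0.10. The list moved up (camera, adjusted p = 2.1e-08, and adjusted p = 0.00996 with an estimated correlation). Of 24 other collagens and matrix glycoproteins, 15 rose and 4 fell in both adjustments, with the basement membrane collagens Col4a1 and Col4a2 up by 1.97 ± 0.09 and 1.84 ± 0.09, Lum by 1.73 ± 0.09 and Col3a1 from 4858 ± 134 to 13760 ± 1579 CPM (SD, n = 4). That list moved up (camera, adjusted p = 1.6e-08), with adjusted p = 0.12 with an estimated correlation. Collagen processing genes were split, 7 higher and 7 lower of 18 in both adjustments, with Loxl4 at a log2 fold change of -1.90 ± 0.10 and P4ha3 at 1.05 ± 0.07 (camera, adjusted p = 0.86). Its median log2 fold change was 0.05, its mean -0.32 and its test direction downward.

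**Figure D3:**
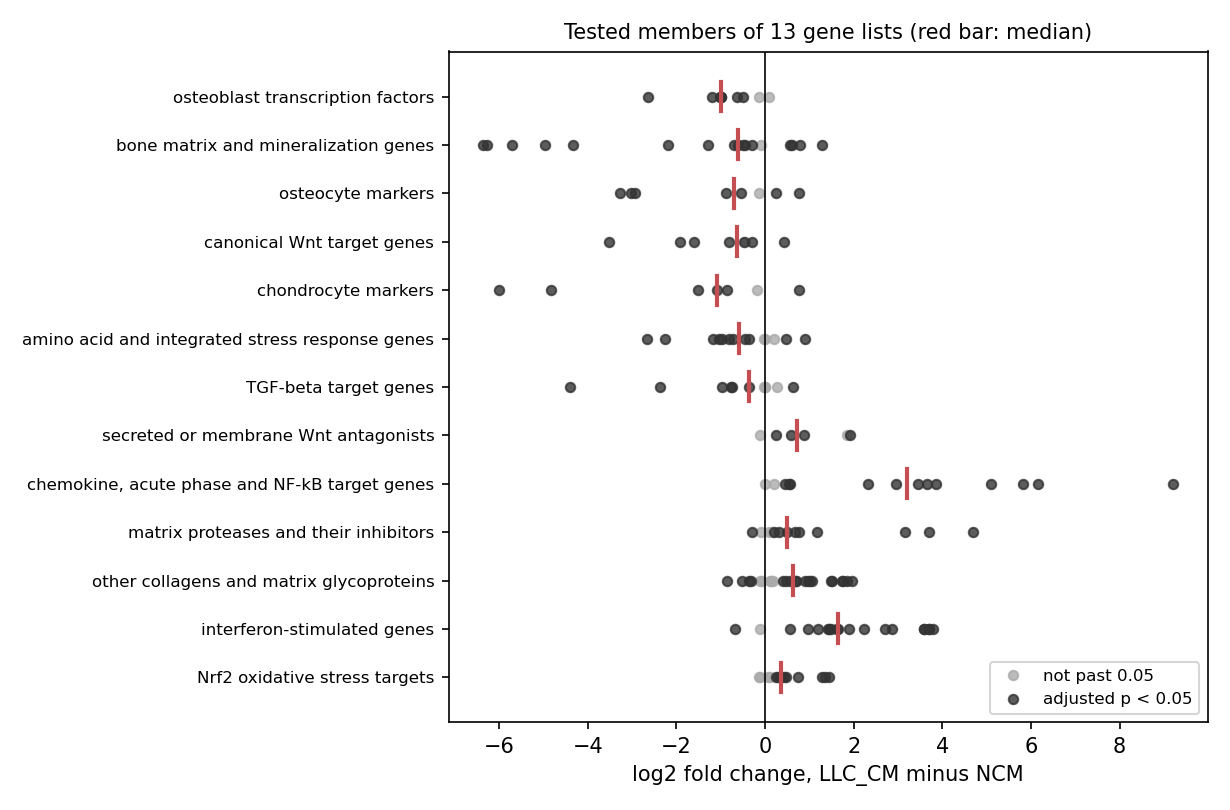
log2 fold changes (LLC_CM minus NCM) of the tested members of 13 gene lists, dark points for an adjusted p under 0.05, grey points for the others and a red bar at the median. The median was -0.98 for osteoblast transcription factors and 3.19 for chemokine, acute phase and NF-kB target genes.

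Amino acid and stress response genes mostly fell, and Nrf2 targets mostly rose. Of 14 tested amino acid and integrated stress response genes, 9 fell and 2 rose in both adjustments, including Asns, asparagine synthetase, at a log2 fold change of -1.05 ± 0.06, Mthfd2 at -1.17 ± 0.07 and Vldlr at -2.66 ± 0.09 (camera, down, adjusted p = 8.5e-05), with adjusted p = 0.12 with an estimated correlation. Of 13 tested Nrf2 targets, 9 rose and none fell in both adjustments, including the heme oxygenase gene Hmox1 by 1.36 ± 0.09 and the metallothioneins Mt1 and Mt2 by 1.27 ± 0.10 and 1.44 ± 0.11 (camera, up, adjusted p = 0.0018), with adjusted p = 0.13 with an estimated correlation. An antisense gene model overlapped 73.5% of Mt2.

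Lists that camera did not call still held changed members. Of all genes tested 36.9% were called, so changed members alone do not set a list apart. Of 25 cell cycle genes 10 rose and none fell (11 rose when adjusted over the list alone), with Mcm3 up by 0.42 ± 0.06 and Tyms by 0.59 ± 0.09 (camera, adjusted p = 0.091, and adjusted p = 0.74 with an estimated correlation). The cell cycle list passed without the low-count filter (0.042) and without LLC_CM replicate 1 (0.040), LLC_CM replicate 2 (0.044) or NCM replicate 4 (0.049), and did not without any of the other 5 libraries, with up to 0.27 without NCM replicate 3. Of 21 cholesterol genes 8 fell and 3 rose (8 and 4 over the list alone), with Dhcr7, an enzyme of cholesterol synthesis, at a log2 fold change of -1.08 ± 0.07 (camera, adjusted p = 0.054, and adjusted p = 0.43 with an estimated correlation). The cholesterol list passed without the low-count filter (0.018) and without LLC_CM replicate 1 (0.048), NCM replicate 1 (0.035) or NCM replicate 3 (0.044), and did not without any of the other 5 libraries, with up to 0.091 without NCM replicate 4. Of 17 endoplasmic reticulum chaperone and unfolded protein response genes, 7 rose and 4 fell (7 and 5 over the list alone), including Pdia6 up by 0.59 ± 0.06 and Xbp1 at -0.47 ± 0.05 (camera, adjusted p = 0.58). Of 25 nuclear respiratory chain genes 8 rose and 1 fell in both adjustments, with Ndufa4 up by 0.54 ± 0.09 (camera, adjusted p = 0.16). Of 20 glycolysis and hypoxia genes 3 rose and 4 fell in both adjustments, with Car9 up by 2.24 ± 0.19 (camera, adjusted p = 0.64). Of 19 MAP kinase and immediate early genes 5 rose and 5 fell in both adjustments, with Jun up by 1.46 ± 0.17 and Egr1 down from 30.2 ± 2.41 to 13.1 ± 1.44 CPM (SD, n = 4; camera, adjusted p = 0.67). Of 9 contractile genes 3 rose and 2 fell (3 and 3 over the list alone), with Tagln at a log2 fold change of -1.07 ± 0.13 and Lmod1 up by 0.61 ± 0.09 (camera, adjusted p = 0.94), and an antisense gene model overlapped 62.4% of Tagln.

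Apart from several chondrocyte markers, markers of other cell types were mostly at low levels. In NCM, Col11a2 averaged 430 CPM, Hapln1 107 CPM and Col2a1 53.9 CPM. Of 7 tested chondrocyte markers 5 fell and 1 rose in both adjustments, with Col2a1, the main collagen of cartilage, at a log2 fold change of -4.82 ± 0.24 and Sox9 up by 0.76 ± 0.07 (camera, down, adjusted p = 8.8e-05, and adjusted p = 0.031 with an estimated correlation). Of 5 tested macrophage markers 3 rose and none fell in both adjustments (camera, adjusted p = 0.38), including Lyz2 by 0.81 ± 0.21 to 20.3 CPM and Fcer1g by 1.54 ± 0.28 from 0.43 CPM. Of 3 tested adipocyte markers Fabp4 rose by 1.37 ± 0.18 and Cebpa by 0.82 ± 0.12, and Plin4 fell by 0.40 ± 0.15 (adjusted p = 0.048) in both adjustments (camera, adjusted p = 0.29). The adjusted p of Plin4 ranged from 0.0029 to 0.24 over 19 other settings and was past 0.05 in 8 of them, losing the call without LLC_CM replicates 1 (0.083), 2 (0.090) or 4 (0.11) and without NCM replicates 1 (0.067), 2 (0.10) or 3 (0.12). Fewer than 3 members were tested for skeletal muscle (2, with Tnnt3 up by 1.87 ± 0.41), endothelial (2, with Vwf at -0.73 ± 0.18) and epithelial markers (1, Muc1, up by 1.93 ± 0.36 to 1.46 CPM), so these lists had no test. None of the 9 mitochondrially encoded genes on the list had a count.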

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

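The measures examined for outlying libraries were fixed by the list of named genes and 6 library measures, and no test in this part was chosen after its result was seen. In 212 groups of 4 libraries, 21 had 1 library so far from the other 3 that the gap to its nearest neighbour exceeded the 95% limit for a share of the group's range, where chance gives about 1 in 20, or 10.6.

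NCM replicate 3 was the outlying library in 9 of the 21. It was the highest NCM library for Prex1 (gap 0.97 of the range, 92.3 CPM against 56.1 to 57.2 in the others), Notum (0.99, 11.8 against 7.65 to 7.71), Col2a1 (0.91, 73.0 against 46.5 to 48.9), Smpd3 (0.91, 701 against 481 to 501), Loxl4 (0.88, 404 against 295 to 309), Dhcr7 (0.86, 55.1 against 48.3 to 49.2) and Col11a2 (0.83, 593 against 358 to 398). It was the lowest for Sfrp2 (0.90, 18.4 against 32.9 to 34.5) and Mcm3 (0.84, 55.8 against 58.3 to 58.7). Without NCM replicate 3, 5130 genes were called and 87.7% of the 5531 genes kept their call.

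Other NCM libraries stood apart in 5 groups. NCM replicate 2 was lowest for Asns (0.96, 116 against 131 to 132 CPM) and Runx2 (0.85, 424 against 481 to 491), and held the single count of Saa3 (1). NCM replicate 4 was lowest for Mt2 (0.90, 87.6 against 125 to 129) and for the share of counts in protein-coding genes (0.85, 96.62% against 96.88% to 96.92%).

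LLC_CM libraries stood apart in 7 groups. Replicate 3 was highest for Enthd1 (0.90, 0.31 against 0.032 to 0.060 CPM) and Loxl4 (0.85, 98.0 against 83.5 to 85.6) and lowest for Lcn2 (0.92, 38.5 against 56.2 to 57.7). Replicate 1 was lowest for Sox9 (0.95, 32.4 against 35.2 to 35.3) and Mmp13 (0.83, 6389 against 7730 to 7996). Replicate 2 was lowest for Alpl (0.90, 12.5 against 14.1 to 14.3) and replicate 4 for Slc6a4 (0.97, 0.12 against 0.22 to 0.23).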

How the results depend on the processing

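The odd or even term, the fits of odd-numbered or even-numbered libraries alone and the shortened bone matrix list were chosen after seeing the data, as was the choice to count a turn of direction in a list without a call. Over 16 planned settings of scaling, filter, tool, block and left-out library, genes changed ranged from 4912 to 5737, genes higher from 2429 to 2940, genes lower from 2445 to 2907 and genes changed at least 2-fold from 1001 to 1658. At an adjusted p of 0.01, 3946 genes were called, and 785 passed the test against a 2-fold change, which asks for more than the fold threshold applied afterwards. No list turned direction under another scaling, and the median of all genes moved by at most 0.013 on the log2 scale. With 2 libraries per group the count was 3034 (1549 higher, 1485 lower) in the odd-numbered and 3145 (1623 higher, 1522 lower) in the even-numbered libraries, and the cause of the lower counts was not tested. Of 100 named genes, 99 stayed on the same side of the threshold in each planned setting that tested them, Plin4 being the exception, and Tnnt3 was not tested with the filter of 1 CPM in 4 libraries.

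Camera with an estimated correlation gave adjusted p = 0.095 for osteoblast transcription factors, 0.070 for osteocyte markers and 0.13 for Wnt targets. The same setting ended 5 more list calls. Fry, which tests a list without comparing it with other genes, called 7 lists that camera did not: Wnt antagonists (4.5e-06), BMP targets (0.0049, down), cholesterol (0.0019, down), endoplasmic reticulum chaperone and unfolded protein response (0.015), respiratory chain (0.021), adipocyte (0.00081) and macrophage genes (0.00081). Without the low-count filter, cell cycle (0.042) and cholesterol genes (0.018) passed. Wnt antagonists ranged from 0.0039 to 0.067 over left-out libraries and reached 0.039 with the odd or even term, and the cause was not tested. Lists near no change turned direction without a call: contractile genes without the low-count filter (0.97) and without NCM replicate 2 (0.95), collagen processing genes with the stricter filter (0.90) and without LLC_CM replicate 2 (0.93), and glycolysis genes without NCM replicate 4 (0.99). Over all 8 left-out libraries, turned or not, their adjusted p ranged from 0.79 to 0.99, from 0.64 to 0.93 and from 0.31 to 0.99. The bone matrix list without Bglap and Bglap2 moved down (4.9e-08).

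The values show no clear pairing of samples by replicate number. Deviations of same-numbered libraries correlated between -0.044 and 0.20, and 3 of 8 libraries correlated best with their own number in the other group. So few libraries cannot exclude a pairing or a shared batch. The replicate block gave 5473 genes and moved Wnt antagonists to adjusted p = 0.022. Among the called genes, 399 had a mean under 1 CPM.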

Other observations

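Tests chosen only after their results were seen were those of a share of mature cells, of amino acid shortage, of macrophage RNA, of tumour cell RNA, of near-identical copies and their summed CPM, and of read assignment and transcription between odd and even libraries, and the intervals required of the amino acid, near-identical copy and cyclic AMP medians and the measured identity of the copies were added later still.

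Antigen presentation genes rose in LLC_CM. All 12 genes of a list of MHC class I and antigen processing genes rose, also when adjusted over the list alone (camera, adjusted over the lists tested in this section, p = 1.5e-16, and adjusted p = 0.017 with an estimated correlation). Among them the immunoproteasome subunit Psmb9 rose by 2.24 ± 0.12 and B2m by 0.67 ± 0.09 on the log2 scale (SE), and the class I heavy chain H2-K1 rose from 48.3 ± 4.39 to 136 ± 7.31 CPM (SD, n = 4). The acute phase and complement lists were chosen after their values had been seen, so no set test is given for them. Of 11 tested acute phase genes 10 rose and none fell in both adjustments, including haptoglobin, Hp, from 142 to 2165 CPM and ceruloplasmin, Cp, from 765 to 2515 CPM. Of 12 tested complement genes 10 rose and 1 fell in both adjustments, with Cfb up by 4.99 ± 0.11 and the inhibitor Cd59a at a log2 fold change of -4.68 ± 0.40, and a gene model on the same strand overlapped 79.5% of Cfb. Of 10 tested fibroblast and stromal progenitor markers 6 rose and 3 fell in both adjustments, with Cd34 up by 1.38 ± 0.28 and Pi16 at -2.87 ± 0.48 (camera, adjusted p = 0.17).

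Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 5531 genes, and the highest of the others gave 3, for the odd against the even numbers. Every other split placed LLC_CM and NCM libraries together on each side. The difference between the groups then counted as spread within a side, so low counts in those splits were built into the comparison. A share of 1 in 35 is also the smallest that it can give. It therefore cannot decide whether chance assignment of these 8 libraries gave the count. The count also says nothing on whether the libraries of a group came from separate cultures.

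Osteoblast transcription factor, bone matrix and osteocyte genes were lower in LLC_CM. Removing the trend of fold change with GC content and transcript length left their median log2 fold change at -0.70 (95% bootstrap interval -1.18 to -0.40) against -0.67 before, which argues against that bias as the whole cause. Amino acid shortage would raise the stress response list, of which 9 of 14 tested members fell and 2, Phgdh and Slc3a2, rose. The list moved down (camera, adjusted p = 8.5e-05), which goes against a shortage, but not with an estimated correlation (adjusted p = 0.12). The median of -0.59 (-1.01 to 0.0042) also has an interval that reaches 0, so a shortage stays undecided. A smaller share of mature cells may contribute but is undecided. The osteocyte median minus the transcription factor median was 0.27 (-2.33 to 1.08), and 5 of 7 tested chondrocyte markers fell as well. Of the 14 called members of these lists 2, Pdpn and Irx5, rose. Such a loss would lower only genes expressed more in mature cells than in the rest, which was not measured here, so these 2 do not decide it. The treatment itself stays open as a hypothesis, since it is the difference the design names.

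Acute phase and complement genes were higher in LLC_CM. Macrophage RNA is argued against, because 7 macrophage-restricted genes summed to at most 0.032 CPM in any LLC_CM library while C3 reached 696 CPM, although Lyz2 and Fcer1g, which are less restricted, rose. For members with a near-identical copy, reads shared within a set of copies are argued against as the cause of the rise. The summed CPM of 7 such sets, which reads moving within a set would leave as it was, had a median log2 ratio of 4.01 (1.14 to 6.92). The 13 members without a copy matching most of their transcript had a median log2 fold change of 2.51 (0.99 to 5.81). The bound of 0 for that interval replaced one of 1 after the value was seen. Because these lists were chosen after their values were seen, a median above 0 in those 13 members was set by the choice and decides nothing. RNA of tumour cells carried over with the medium could not be excluded, as no LLC1 profile was used here. Epithelial markers summed to 2.80 times the NCM level, but at only 1.59 to 2.49 CPM in LLC_CM against 0.49 to 0.92 CPM in NCM. Most of these reads were of Muc1 (190 counts over LLC_CM, 45 over NCM), the only marker with enough reads to test. The need for 3 testable markers was set after this ratio was seen. Krt8, Krt18 and Epcam had 0 counts in every library. The ratio is thus no measure of carry-over on the scale of C3. A response of the osteoblasts to the medium is a hypothesis that these tests leave open.

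Rpl37a was lower, and Mir682 and Gm4149 higher, in the odd-numbered libraries of both groups. Rpl37a, a ribosomal protein gene, averaged 311 CPM in odd and 770 CPM in even libraries, Gm4149 526 and 147 CPM, and Mir682 261 and 42.7 CPM. Assignment of one transcript's reads to different copies is a candidate explanation, as Gm4149 matched Rpl37a at 99.6% identity over 274 bases and the log2 ratio of the summed CPM was 0.20 against -1.31 for Rpl37a alone. A general difference in transcription is argued against, since only 3 genes passed an adjusted p of 0.05 in edgeR, with 438 at an unadjusted p under 0.05. The comparison of LLC_CM with NCM gave 5343 genes with the odd or even number as a term, against 5531 without it.

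As a hypothesis, signalling through STAT3 and C/EBP factors may accompany the acute phase rise. In a list whose values had not been seen, 7 of 9 tested genes rose and 1 fell, including Osmr by 2.36 ± 0.10 and Socs3 by 1.76 ± 0.07, while Pim1 fell by 1.14 ± 0.14 (camera, adjusted p = 4.7e-08, and adjusted p = 0.031 with an estimated correlation). As a further hypothesis, cyclic AMP and parathyroid hormone response genes could rise with Mmp13 and Il6, since such signals also lower Tnfrsf11b. Only 2 of 10 tested genes rose and 4 fell, among them Nr4a1 at -0.78 ± 0.13 and Nr4a2 at -1.21 ± 0.13 (camera, adjusted p = 0.29). These values met the bound set beforehand for excluding it, but the median of -0.12 (-0.78 to 0.49) did not lie below 0 by more than its spread, so it stays undecided.

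All 37 genes of the mitochondrial chromosome in the table had 0 counts in all 8 libraries, while 6 mitochondrial gene copies annotated on chromosome 1 held between 8952 and 16213 counts per library.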
